A study of Rattus norvegicus with 20 samples.

How the data were processed

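RNA from snap-frozen brain tissue was measured in 20 samples of 10 rats, 1 ipsilateral and 1 contralateral to a cortical impact in each animal. Per the labels' protocols, RNA was hybridised to a probe panel and counted on an nCounter Digital Analyzer without amplification, and handled in nSolver, whose version is not given in the sources used here. The deposited matrix holds whole-number counts per probe: 784 rows, of which 750 are endogenous genes, 20 were taken as housekeeping genes, 8 are negative and 6 positive controls. The files do not mark housekeeping rows. They were recognised as the separate alphabetical block that precedes the controls, whereas the series design text speaks of 10 housekeeping controls.

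The series design text describes normalization to the positive and negative controls and to housekeeping genes, and the matrix is named as normalized. The deposited counts do not have this form. Positive control geometric means differ 2.09-fold between libraries, totals over 770 probes differ 9.29-fold, negative controls are present and not subtracted, and the lowest of the whole-number values is 1. The values were therefore treated as raw counts. The design fixed before the data were examined had planned limma on normalized values and edgeR for raw counts, so edgeR was used. A second table of the series holds the same deposited counts without the 14 control rows, but in 20 of 20 columns under another animal number of the same hemisphere. Pairs of hemispheres are the same in both tables. Animal numbers here follow the column headers of the matrix, and a different number would not change a paired comparison.

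Counts were scaled by the geometric mean of the 17 housekeeping genes with a mean count of at least 20. Edc3, Rpl19 and Tubb5, with means of 3.30, 8.40 and 10.4 counts, were left out. After scaling, Gusb was 1.04 higher and Oaz1 0.44 lower (-0.44) on the log2 scale ipsilaterally, the largest differences among the 17. Endogenous genes with a mean raw count of at least 20 were tested, 193 of 750 (25.7%). The other 557 lie near the negative controls, whose highest count was 18. Group means ± SD are of scaled counts, and counts per animal compare log2(scaled count + 1). A scaled count is raw count divided by the library's factor, which ranged from 0.289 to 4.27.

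Hemispheres were compared with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood test (glmQLFit, glmQLFTest), the animal as a block, two-sided, and Benjamini-Hochberg adjustment over the 193 genes. A gene was called at adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. The block follows from the titles, which give the same animal number to 1 sample of each hemisphere. It removes what both hemispheres of an animal share, whereas an effect of the unlabelled treatment on 1 hemisphere alone stays. Residuals of the 2 libraries of an animal correlated from -0.21 for animal 6 to 0.50 for animal 10, above 0.1 in 5 of 10 animals. Only for animals 10 and 11 did the ipsilateral library correlate best with the contralateral library of the same animal. The pairing therefore rests on the titles. The biological coefficient of variation was 0.247. Gene lists fixed before the data were examined (36, of which 14 had at least 3 tested members) were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry. The other 22 lists had fewer than 3 tested members and were not tested.

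Genes are named by a rule fixed in advance. It takes the 12 largest increases and 12 largest decreases among called genes with the same direction in at least 9 of 10 animals, of which 9 decreases were found. It adds up to 4 members with the smallest p from each tested list, and 20 genes fixed by name. Not every gene the rule allows is printed, some are not reported here, and genes outside the rule appear only among the closing observations, where this is said.

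Libraries of a group were compared for duplicates. The chi-square statistic per degree of freedom lay between 1.60 and 55.4 for all pairs, so no library was taken as a repeat of another. On simulated counts with the real means and library sizes (10 simulations of 202 genes, 40 changed in each), edgeR recovered 68.4% of 1.5-fold and 100% of 2-fold and 4-fold changes. Of its calls, 3.24% fell on unchanged genes. Camera called a simulated list of 6 genes raised 2-fold in 10 of 10 simulations at unadjusted p under 0.05 and a list of unchanged genes in 0 of 10. Simulated changes were equal in all animals and went either way at random, with a dispersion of 0.06, unchanged housekeeping genes and independent genes. The real responses were uneven between animals and mostly higher, Gusb differed by 1.04, and estimated inter-gene correlations reached 0.836 (interferon response). These rates therefore need not hold for the real data.

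Alternatives fixed in advance were the fit without the block, the animal as a random block (limma), a pseudocount of 10 (limma), no filter, a mean count of at least 50, median centring, the second table, the fit without trend, the robust fit, an exact Wilcoxon signed-rank test, a 2-fold minimum, and leaving out each animal. Added after the data were seen were limma on log2(scaled count + 1), DESeq2 1.42.0 with either set of factors, TMM, all 20 housekeeping genes, the set without Gusb, subtraction of the negative control mean plus 2 SD, the fit without animals 8 and 10, which hold the libraries with the lowest totals, the count of genes called under 6 scalings and, under each of these, the count of called genes changed at least 2-fold. Those 6 are the 17 housekeeping genes, all 20, the 17 without Gusb, TMM, DESeq2's size factors and median centring, each in edgeR. For background subtraction the housekeeping factors were recomputed from the subtracted counts. Figures and checks used Python with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

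The gene names are those of the matrix. Of the accessions of 770 probes, 0 matched a rat transcript in a RefSeq table of the GRCr8 assembly, and 705 of 770 names equal a rat gene symbol. The organism for which the probes were designed is not given in the sources used here, and no genome position is reported. A probe that binds the rat transcript poorly would lower a gene's count in both hemispheres alike, so levels are compared between hemispheres and not between genes.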

Results

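RNA was counted in brain tissue of 10 female rats after a controlled cortical impact, a piston-driven contusion of the exposed cortex used as a model of traumatic brain injury. Each animal gave 1 sample from the injured (ipsilateral) hemisphere and 1 from the opposite (contralateral) hemisphere, so that the 20 libraries form 10 pairs. The assay was the NanoString nCounter, in which barcoded probes bound to RNA are counted singly without amplification. The panel held 750 endogenous genes and 20 further genes taken here as housekeeping genes. The total count over these 770 probes ranged from 34454 in the contralateral library of animal 10 to 319964 in the contralateral library of animal 7. It averaged 98154 ± 33430 (SD, n = 10) in the ipsilateral and 114018 ± 90001 (SD, n = 10) in the contralateral libraries. The 8 negative control probes, which have no target, averaged 5.79 ± 1.31 (SD, n = 10) ipsilateral and 4.76 ± 1.20 (SD, n = 10) contralateral counts. The median endogenous probe had a mean of 5.85 counts, so most of the panel lay at this background. The 193 genes with a mean count of at least 20 were tested.

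**Figure D1:**
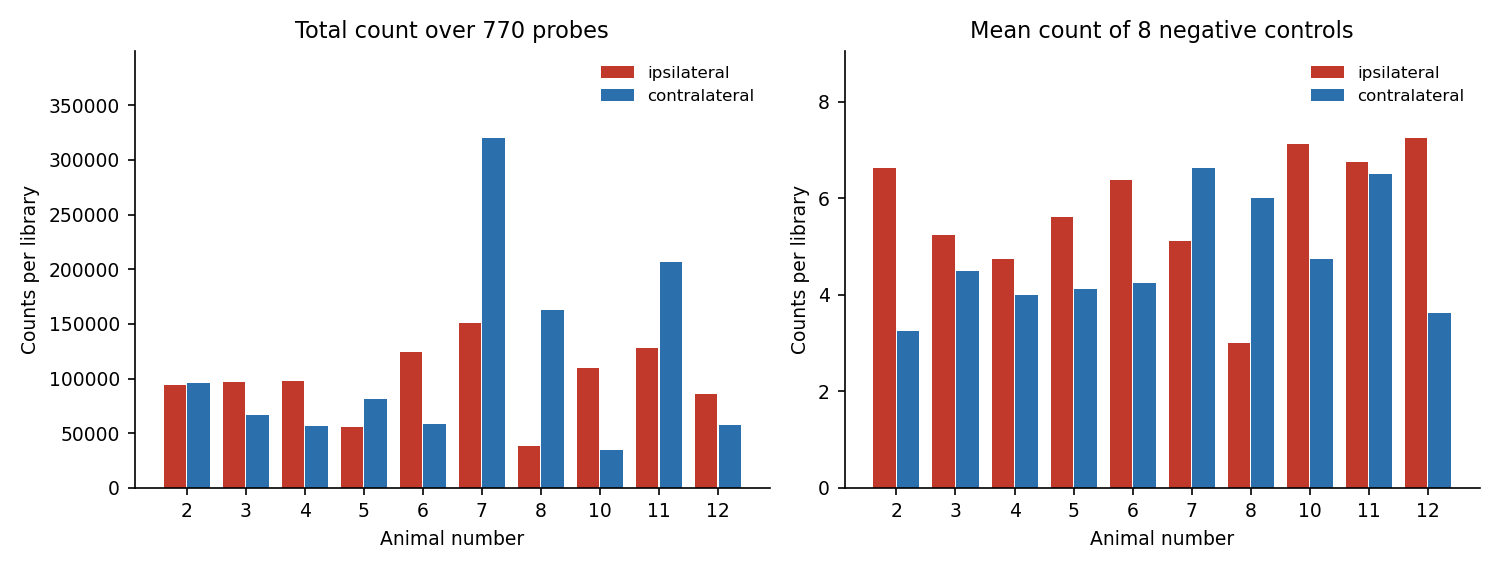
Left, total count per library over the 770 endogenous and housekeeping probes (vertical axis, counts) for each animal (horizontal axis), with 1 red bar per ipsilateral and 1 blue bar per contralateral library; right, the mean count of the 8 negative controls in the same libraries. Totals span 34454 to 319964 counts, and negative control means span 3 to 7.25 counts.

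The comparison of the hemispheres asks which transcripts differ between the injured side and the uninjured side of the same brains. Lgals3 (galectin-3, a lectin of activated macrophages and microglia) was 12.03-fold higher, with 355 ± 302 scaled counts ipsilaterally and 22.2 ± 11.1 contralaterally (SD, n = 10 each; log2 fold change 3.59 ± 0.48 SE, edgeR adjusted p = 0.000715), and was higher in 10 of 10 animals. The increase was uneven, with 20.5 to 22.7 ipsilateral scaled counts in animals 3, 5 and 10 and 174 to 818 in the other 7 animals. Cd68, a lysosomal protein of phagocytes, was 6.29-fold higher (143 ± 104 against 18.8 ± 6.1 scaled counts, SD, n = 10 each), again in 10 of 10 animals (edgeR adjusted p = 0.000715). The increase of Cd68 was small in animal 3 (16.2 against 13.7 scaled counts) and animal 5 (21.1 against 15.1). In animal 5 its raw count was lower ipsilaterally, with library factors of 0.616 against 1.06. The direction in that animal therefore rests on the scaling. Vim, the intermediate filament vimentin of reactive glia and fibroblasts, was 4.79-fold higher in 9 of 10 animals (139 ± 114 against 23.4 ± 7.9 scaled counts, SD, n = 10 each; edgeR adjusted p = 0.0011). Contralateral counts of these 3 genes lay near background, so the sizes of their fold changes are uncertain. In contralateral animal 10, Lgals3 and Cd68 (9.01 each) and Vim (6.76) lay below the scaled negative control mean of 10.7. After background subtraction, with recomputed housekeeping factors, log2 fold changes were 4.48 for Lgals3, 3.50 for Cd68 and 2.76 for Vim, against 3.59, 2.65 and 2.26 before. In all, 111 of the 193 tested genes differed between hemispheres (edgeR, adjusted p under 0.05), 91 of them higher and 20 lower on the injured side. With this housekeeping scaling 34 of them changed at least 2-fold, 34 higher and 0 lower. The called genes with such a change numbered 20 higher and 2 lower (Egr1 and Map2k4) under TMM scaling, and 14 higher and 5 lower with each library centred on its median.

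Further genes were among the 12 largest increases of called genes that were higher in at least 9 of 10 animals. The log2 fold change was 2.68 ± 0.46 (SE) for Anxa1 (annexin A1, a mediator of the resolution of inflammation), 2.44 ± 0.49 for A2m (the protease inhibitor alpha-2-macroglobulin) and 2.39 ± 0.52 for Col3a1 (fibrillar collagen), each in 9 of 10 animals. It was 1.71 ± 0.33 for Lyz2 (lysozyme of myeloid cells), 1.47 ± 0.24 for Fn1 (fibronectin) and 1.34 ± 0.25 for Il13ra1 (a subunit of the interleukin-13 receptor). The edgeR adjusted p of these 6 genes lay between 0.0011 for Anxa1 and 0.00294 for Col3a1. Fn1 and Il13ra1 were higher in 10 of 10 animals.

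**Figure D2:**
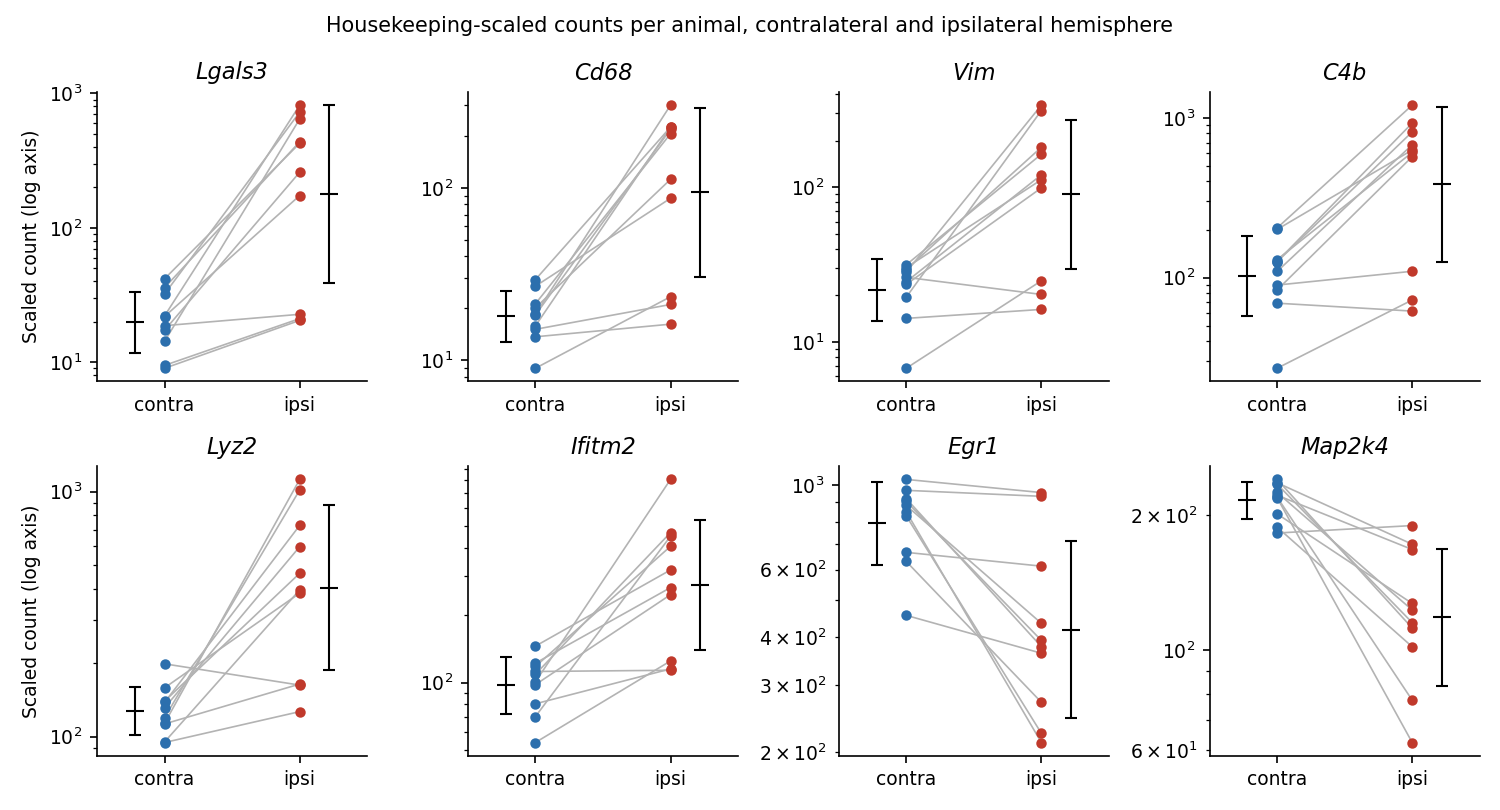
Housekeeping-scaled counts (vertical log axes) of 8 genes in the contralateral (blue) and ipsilateral (red) library of each of 10 animals, with a grey line joining the 2 libraries of an animal; black bars give the mean ± SD computed on log2(scaled count + 1). Scaled counts of Lgals3 and Cd68 rise in 10 of 10 animals, those of Cd68 only slightly in animals 3 and 5. Egr1 falls in 10 of 10, and the steepness of the lines differs between animals.

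The lists with the highest median log2 fold changes were microglia and macrophages (1.66), antigen presentation (1.09), interferon response (1.05), complement (1.04), and phagocytosis, lysosome and Fc receptors (1.02). Of the microglia and macrophage markers, 3 of the 9 on the panel were abundant enough to test, and all 3 rose: Cd68, Ptprc (the leukocyte antigen CD45, log2 fold change 1.66 ± 0.33 SE) and Fcer1g (the common Fc receptor gamma chain, 1.35 ± 0.24 SE). In the list of phagocytosis, lysosome and Fc receptor genes, 6 of 7 tested members rose, among them the cholesterol exporter Abca1 (1.20 ± 0.22 SE), the lipid carrier Apoe (1.02 ± 0.24 SE) and the lysosomal protease Ctss (0.66 ± 0.11 SE). Apoe had 19529 ± 7642 ipsilateral against 9049 ± 1774 contralateral scaled counts (SD, n = 10 each). Of 3 tested complement genes, 2 rose: C4b, a component of the classical pathway (2.00 ± 0.30 SE), and the receptor C3ar1 (1.04 ± 0.26 SE). All 4 tested antigen presentation genes rose, with log2 fold changes of 1.30 ± 0.24 (SE) for Psmb8 and 1.06 ± 0.26 for Psmb9, both subunits of the immunoproteasome, and 1.12 ± 0.22 for Cd74, the invariant chain of class II molecules. Without the animal block the edgeR adjusted p of Cd74 was 0.050 and its call was lost. All 6 tested interferon response genes rose, including Ifitm2 (1.502 ± 0.259 SE), Ifi44 (1.20 ± 0.27 SE), the RNA sensor Ifih1 (0.91 ± 0.21 SE) and the transcription factor Irf1 (0.73 ± 0.17 SE). The calls of Ctss and Irf1 were lost when each library was centred on its median. Ptprc, Apoe, C3ar1, Psmb8 and Irf1 were higher in 8 of 10 animals, and the other genes named in this paragraph in at least 9. The minimum of 20 averaged both hemispheres, so a gene low contralaterally was tested only if high ipsilaterally. Cd68, Ptprc, C3ar1, Psmb8 and Psmb9 averaged under 20 scaled counts contralaterally and over 20 ipsilaterally. This filter favours raised members and higher list medians. Tested were 3 of 26 complement, 4 of 14 antigen presentation and 6 of 29 interferon genes on the panel. At a minimum of 50 the microglia, complement and antigen presentation lists were not tested.

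Lists of endothelial genes and secreted signals had lower medians, 0.62 for endothelial cells and 0.50 for chemokines. All 4 tested endothelial and blood-brain barrier genes were higher: the junction protein Cdh5 (log2 fold change 0.98 ± 0.20 SE), the receptors Tie1 (0.65 ± 0.15 SE) and Tek (0.37 ± 0.10 SE), and the efflux transporter Abcb1a (0.59 ± 0.18 SE). The log2 fold change of Tek was -0.08 with median centring, and only Cdh5 of these 4 was called under each of 6 scalings. Of 4 tested chemokine genes 3 rose, namely Cxcl12 (0.53 ± 0.12 SE), Cxcl5 (0.79 ± 0.22 SE) and Ccl2 (0.47 ± 0.19 SE, edgeR adjusted p = 0.0497). The call of Ccl2 was lost when any of 7 single animals was left out, as it was without animal 7 (0.32, edgeR adjusted p = 0.145). In the list of pro-inflammatory cytokines and signalling, 2 of 4 tested members rose, Il6st (a signal-transducing receptor subunit, 0.52 ± 0.15 SE) among them, and 1 fell, the prostaglandin synthase Ptgs2. Among genes tied to anti-inflammatory signalling and repair, 4 of 7 rose: Lgals3, Mrc1 (the mannose receptor of macrophages, 1.33 ± 0.33 SE), Tgfb1 (1.21 ± 0.19 SE, 10 of 10 animals) and Stat3 (0.57 ± 0.13 SE). With median centring the calls of Cxcl12, Cxcl5, Ccl2, Il6st and Stat3 were lost. Those of Cxcl12, Ccl2, Il6st and Stat3 were lost with DESeq2's size factors too, those of Ccl2 and Il6st also under TMM, and that of Ccl2 also with all 20 housekeeping genes. Of the 4 chemokine genes, 2 were called higher under TMM and 0 with median centring. Of the 4 pro-inflammatory genes, 0 were higher and 1 was lower under either of these scalings.

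Other lists were mixed. In the Toll-like receptor and NF-kB pathway, 4 of 13 tested genes rose (2 when adjusted over the list alone), with log2 fold changes of 0.98 ± 0.18 (SE) for Ly96, the lipopolysaccharide co-receptor, and 0.82 ± 0.26 for Nfkb2. Without animal 7 the call of Nfkb2 was lost (edgeR adjusted p = 0.0509). Of 5 tested cell death genes 2 rose, and 1 when adjusted over the list alone. Of 3 tested autophagy genes 2 rose, including the lysosomal membrane protein Lamp2 (0.50 ± 0.13 SE), and of 4 tested neurodegeneration-associated genes 2 rose, Apoe and the chaperone Clu (0.83 ± 0.18 SE). The calls of Nfkb2 and Lamp2 were lost under TMM scaling, with DESeq2's size factors and with median centring. Under TMM 1 of the 13 Toll-like receptor and NF-kB genes was called higher (Ly96) and 0 lower, and with median centring 1 was higher and 2 lower. Of the cell death genes 0 were higher under TMM or median centring, and of the autophagy genes 0 as well, while median centring called 1 of each lower. Of the neurodegeneration-associated genes 2 stayed higher, with 1 lower under TMM and 2 lower with median centring. Median centring also called 1 complement gene and 2 of the genes tied to anti-inflammatory signalling and repair lower. For every other list the counts adjusted over the list alone equalled those adjusted over all tested genes.

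**Figure D3:**
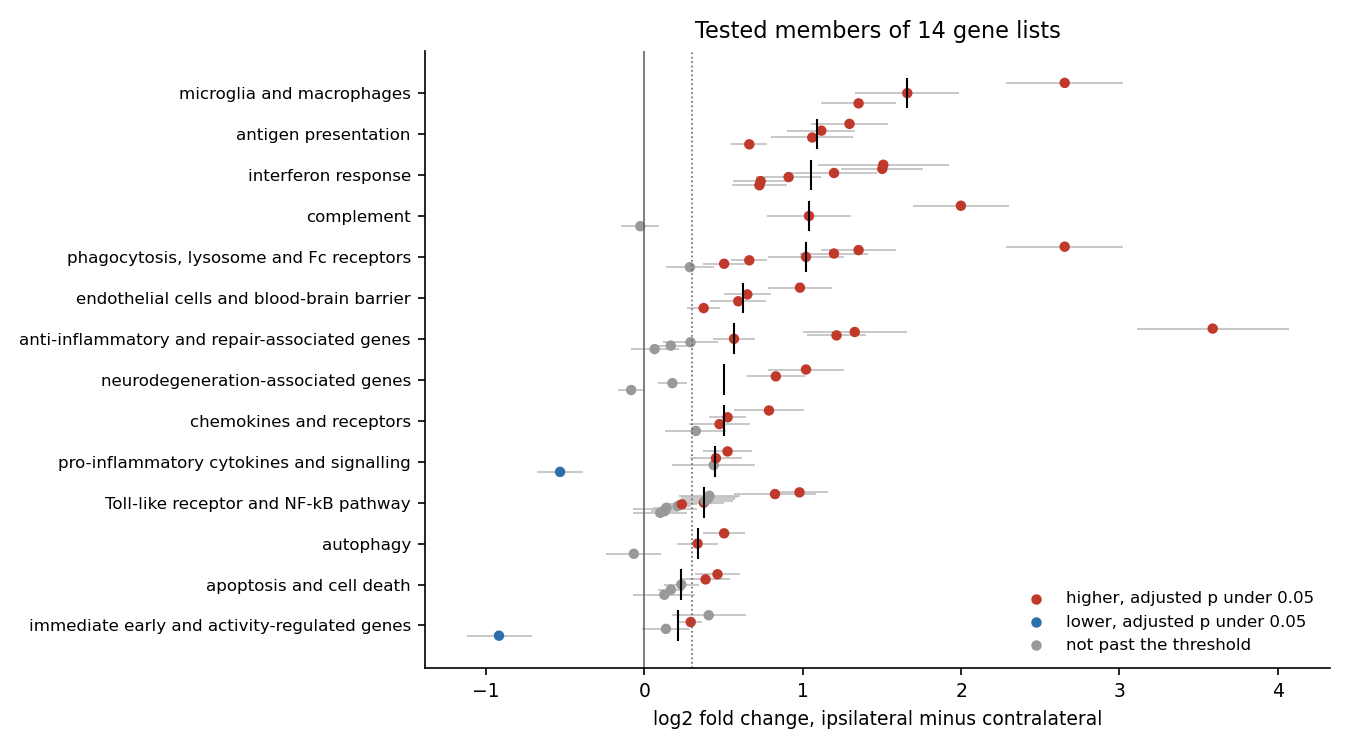
Fitted log2 fold change (horizontal axis, ipsilateral minus contralateral) of each tested member of 14 gene lists, with the SE as a grey bar, a black line at the list median and a dotted line at the median of all 193 tested genes (0.30); red members were called higher, blue lower and grey did not pass. The microglia and macrophage list has the highest median (1.66), and the immediate early list holds members on both sides of 0.

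How many genes were lower on the injured side depended on the scaling, with 20 called after housekeeping scaling, 47 after TMM and 71 after median centring. The values that follow are from housekeeping scaling. Egr1, an immediate early transcription factor induced by neuronal activity, fell in 10 of 10 animals, from 815 ± 177 contralateral to 477 ± 272 ipsilateral scaled counts (SD, n = 10 each; log2 fold change -0.92 ± 0.21 SE, edgeR adjusted p = 0.0033). The related factor Egr3 fell by 0.57 ± 0.17 (SE) on the log2 scale, and the prostaglandin synthase Ptgs2, which neurons also express with activity, fell by 0.53 ± 0.15 (SE). The kinase genes Map2k4 and Map3k5 fell as well, with log2 fold changes of -0.84 ± 0.15 (SE) and -0.32 ± 0.10 in that order. Cyfip2, a regulator of actin at synapses, had -0.59 ± 0.17 (SE), and Mpped1 had -0.63 ± 0.18. The cytokine Mif had -0.25 ± 0.09 (SE). Each of these genes was lower in at least 9 of 10 animals. Leaving out any of 5 single animals ended the call of Mif (edgeR adjusted p up to 0.0835, without animal 11), as did leaving Gusb out of the scaling (0.0713).

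With housekeeping scaling, immediate early genes did not move together. In this list of 4 tested genes, Egr1 fell and Jun rose (log2 fold change 0.29 ± 0.07 SE, 10 of 10 animals, edgeR adjusted p = 0.00597), while Fos stood at 0.14 ± 0.15 (SE, edgeR adjusted p = 0.445). The remaining member did not pass either. With median centring all 4 members lay below 0, with Egr1 at -1.37, Jun at -0.16 and Fos at -0.31. The sign of every member but Egr1 therefore depends on the scaling. Of the 6 scalings, only the 17 housekeeping genes and that set without Gusb gave a call for Jun. The angiogenic factor Vegfa, at -0.16 ± 0.10 (SE, edgeR adjusted p = 0.184), did not pass with housekeeping scaling or without Gusb (0.396). It was called lower under the other 4 of 6 scalings, at -0.27 (0.0370) with all 20 housekeeping genes, -0.44 (0.00543) with TMM, -0.47 (0.00501) with DESeq2's size factors and -0.61 (0.00172) with median centring.

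As sets, none of the 14 lists with at least 3 tested members passed camera, which compares a list with the other tested genes (0 at adjusted p under 0.05, 4 at unadjusted p under 0.05). The lowest adjusted p was 0.0597, for phagocytosis, lysosome and Fc receptors, followed by 0.0825 for microglia and macrophages, antigen presentation and interferon response. With an estimated correlation, camera gave adjusted p = 0.789 at the lowest. The fry test, which asks whether a list moves on balance one way without comparing it with other genes, called 12 of 14 lists, all toward higher values. It was run with housekeeping scaling only. There the tested genes as a whole leaned higher, so the 12 calls cannot be told apart from this general shift. Medians of the 14 lists ran from 0.21 to 1.66, against 0.30 for all tested genes. The direction that camera gave was lower for pro-inflammatory cytokines and signalling (median log2 fold change 0.44, mean 0.22), since camera sets a list against the other tested genes. It was also lower for immediate early genes (median 0.21, mean -0.02).

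The share of higher among called genes was 82.0% with housekeeping scaling, 55.2% with TMM (58 higher, 47 lower) and 36.0% with each library centred on its median (40 higher, 71 lower). Under 6 scalings, 52 genes were called in the same direction, 40 higher and 12 lower, including all 12 of the most raised genes named here. The 12 lower genes include Egr1, Egr3, Ptgs2, Map2k4, Map3k5, Cyfip2 and Mpped1, and Mif is not one of them. The median log2 fold change of all tested genes was 0.30 with housekeeping scaling, 0.02 with TMM and -0.15 with median centring. Without the animal block 109 genes were called, 96 higher and 13 lower. Ipsilateral libraries were counted in one set and contralateral libraries in another, with positive control counts 1.45-fold higher in the ipsilateral set, so the set and the hemisphere cannot be told apart.

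Several genes central to neuroinflammation lay under the minimum count. Mean raw counts were 6.15 for Tnf, 7.35 for Il1b, 4.70 for Il6, 4.05 for Il10 and 2.10 for Itgam, close to the negative control mean of 5.28, and none was among the 193 tested. C3 (11.6) and Pecam1 (14.7) also lay under the minimum of 20. Of the 36 gene lists, 22 had fewer than 3 tested members. They include neutrophils (0 of 8 on the panel tested), T and NK cells (1 of 16), B and plasma cells (1 of 10), astrocytes (1 of 2) and neurons (2 of 2). No oligodendrocyte, glutamatergic or GABAergic marker of the lists was on the panel, nor were Gfap, Aif1, Mbp, Bdnf, Hmox1 or Rbfox3.

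Some of these animals received intranasal human neural stem cells, immortalised with L-myc, and others vehicle. The labels do not say which animal received which, so no comparison of the treatments was made. The hemisphere differences reported here are over all 10 animals, whatever their treatment.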

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

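All tests of explanations in this part were chosen after the results were seen. The outlier check compared the most extreme library of each group of 10 with the nearest other, for 57 named genes and 5 library measures per hemisphere. By chance it picks out about 1 in 20 groups, 6.2 of the 124 examined, and it picked out 6.

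The ipsilateral library of animal 8 had a housekeeping geometric mean of 47.5 counts against a group median of 165 (gap of 0.488 of the group's log2 range) and a negative control mean of 3 against 6 (gap 0.521). The contralateral library of animal 6 had the highest Abca1 of its group, 463 scaled counts against a median of 325 (gap 0.552), and the lowest Col1a1, 2.80 against 12.5 (gap 0.638). Vim was lowest in the contralateral library of animal 10, at 6.76 scaled counts against a median of 25.3 (gap 0.469). Abcb1a was lowest among ipsilateral libraries in animal 3, at 27.6 against a median of 66.8 (gap 0.529).

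The first pattern is the 111 called genes and their lean toward higher values on the injured side. Chance is argued against as the source of the number. When hemisphere labels were swapped within animals, 1 of 100 arrangements, the real one, gave as many. The highest of the others gave 100, with animal 10 alone swapped. Not all 512 possible arrangements were examined, and some of the rest could give as many, so chance is not excluded. After scaling, the negative controls averaged 6.67 ± 2.12 ipsilateral and 4.68 ± 2.63 contralateral counts (SD, n = 10 each). This enlarged background is argued against as the only source of the higher values, since 91 of 91 higher genes stayed above 0 after background subtraction. Their median log2 fold change was 0.898 against 0.779 before. The housekeeping factors were recomputed from the subtracted counts, and abundant genes rose too (Clu from 0.830 to 0.898, Apoe from 1.02 to 1.09). The rise of the median therefore mixes 2 changes and says nothing about background. Subtraction ended 17 of the 91 higher calls because the spread grew, with a median SE of 0.296 against 0.177 and a median log2 fold change of 0.602 against 0.538. Whether the lean toward higher genes comes from the scaling cannot be told apart from a real shift. TMM, under which 55.2% of the called genes were higher, centres the tested genes near 0 and so brings this balance about itself. The separate sets, with positive controls 1.45-fold higher in the ipsilateral one, cannot be told apart from the hemisphere, and the injury itself stays open as a biological explanation.

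The second pattern concerns 3 ipsilateral libraries that lay within the contralateral range on the first principal component (PC1, 74.9% of the variance of log2 scaled counts). They scored 5.24 (animal 3), 4.85 (animal 5) and 3.92 (animal 10), against 3.07 to 7.90 for the contralateral libraries and -13.1 to -4.99 for the other 7 ipsilateral ones. An exchange with a contralateral library is argued against, since the contralateral score nearest to the injured side was 3.07 and none was out of place. Low RNA input is argued against for animals 3 and 10, whose ipsilateral scale factors were at least 1.23 against a group median of 1.005, but cannot be told apart from other sources for animal 5 (0.616), where a single library is too little to decide. A milder lesion, tissue taken outside the lesion, the unlabelled treatment or a sample from outside the series may each account for these scores, and none was tested.

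The third pattern is that most probes read at the level of the negative controls. Too little RNA cannot be told apart from other sources. The percent of endogenous probes above the negative control mean plus 2 SD ran from 24.7% to 42.8% and had a rank correlation of 0.365 with the housekeeping counts over 20 libraries (p = 0.114), which decides neither way. Probes that detect the rat transcript poorly cannot be told apart from low expression either. Of 18 microglial and endothelial markers on the panel, 11 (61.1%) had a mean below the highest negative control count, against 538 of the other 732 endogenous probes (73.5%, Fisher p = 0.281). The 18 markers are too few to decide. The other probes belong to the same panel, so poor detection shared by all probes would not show in this comparison. Of the 20 genes taken as housekeeping, 17 had a mean of at least 20, while Edc3, Rpl19 and Tubb5 had 3.30, 8.40 and 10.4. Low expression of many immune genes in brain stays open and was not tested.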

How the results depend on the processing

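The alternatives added after the data were seen are DESeq2, limma with pseudocount 1, TMM, other housekeeping sets, background subtraction, the fit without animals 8 and 10, the 6-scaling count and the 2-fold count under each scaling. The total of 111 calls stayed within 1.5 times under every other test, scaling and filter tried (80 to 120). The genes called changed more than the total. Of the 111 main calls, 78 were also called with TMM, 75 with DESeq2's own size factors and 63 with median centring. A 2-fold minimum left 34 with or without adjustment (34 higher, 0 lower). That 2-fold count was 22 with TMM (20 higher, 2 lower), 19 with DESeq2's size factors in edgeR (17 and 2) and 19 with median centring (14 and 5). It was 29 with all 20 housekeeping genes (28 and 1) and 36 without Gusb (36 and 0). Leaving out 1 animal gave 81 (without animal 7 or 11) to 126 calls (without animal 3), 70 to 105 higher and 9 to 23 lower. The direction split moved with scaling: 58 higher and 47 lower with TMM, 55 and 48 with DESeq2's own size factors, and 40 and 71 with median centring. The 20 lower genes became 13 without the replicate block, 9 without a filter, 10 with the Wilcoxon test, 12 without Gusb, 9 with background subtraction and 12 without animals 8 and 10. The cause was not tested. No filter left 16 genes called under all 6 scalings (12 higher, 4 lower) instead of 52, with 750 genes tested. Without animals 8 and 10 that count was 45 (37 higher, 8 lower), and with 1 animal left out 42 to 61.

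Camera called 0 lists in the main fit, 3 without a filter, 1 at a mean of at least 50, 3 with median centring, 3 with TMM, 3 with all 20 housekeeping genes, 2 with background subtraction, 3 without animals 8 and 10, and 0 to 2 with 1 animal left out (2 without animal 5 or 10, 1 without animal 7). Phagocytosis, lysosome and Fc receptors was called by camera in each of these settings with any call, but not in the main fit (camera adjusted p = 0.0597) or with an estimated correlation (0.789). Fry, run on the main fit alone, called 12 lists. Of the 111 calls, 16 turned sign with median centring (3 of them passing the other way), 5 with TMM and 6 with DESeq2's size factors in edgeR (0 passing in either). Of 57 named genes, log2 fold changes turned sign for Tek (-0.079), Jun (-0.16) and Fos (-0.31) with median centring, for Jun (-0.020) and Fos (-0.18) with DESeq2's own size factors and for Fos (-0.14) with TMM. Over 28 alternatives, named genes kept direction and side of the threshold in 1487 cases, lost the call in 80 and gained it in 10. The replicate block changed the call of Cd74 (adjusted p = 0.050 without it) and Nefl (0.0944) and of no other named gene. At the real library sizes simulated 1.5-fold changes, equal in all animals, were recovered in 68.4% of cases. Other depths and uneven responses were not simulated.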

Other observations

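The genes in this paragraph lie outside the naming rule and were chosen after their values were seen. Besides the matrix and lysosome genes of the report, the fibrillar collagen Col1a1 was higher ipsilaterally (log2 fold change 1.85 ± 0.45 SE, 8 of 10 animals, edgeR adjusted p = 0.00494). The tetraspanin Cd63 of late endosomes (1.12 ± 0.21 SE) and the lysosomal protease Ctsh (1.11 ± 0.20 SE) were each higher in 9 of 10 animals (edgeR adjusted p = 0.00124 and 0.00116). These 3 genes were called under each of 6 scalings, as was the receptor Notch1 (0.74 ± 0.13 SE, 9 of 10 animals). The matrix receptor subunit Itgb1 (0.60 ± 0.13 SE, 9 of 10 animals) lost its call with median centring.

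The 3 genes in this paragraph were also chosen after their values were seen. Nefl, the light neurofilament chain, had a log2 fold change of -0.31 ± 0.12 (SE, 8 of 10 animals lower, edgeR adjusted p = 0.0397), which did not pass when any of 7 single animals was left out (up to 0.0846, without animal 6) or with scaling without Gusb (0.0605). Syt17, a synaptotagmin, had -0.41 ± 0.15 (SE, 8 of 10 animals lower, edgeR adjusted p = 0.0302) and did not pass without animal 2, 7 or 11 (0.0635 to 0.0709). Thy1, a surface protein of neurons, had -0.44 ± 0.22 (SE, 7 of 10 animals lower, edgeR adjusted p = 0.0948) with housekeeping scaling and -0.72 with TMM (edgeR adjusted p = 0.0192).

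The size of the hemisphere difference varied between animals. Ipsilateral Lgals3 was 818 scaled counts in animal 8, 726 in animal 6, 645 in animal 7, 436 in animal 11, 426 in animal 4, 259 in animal 12, 174 in animal 2, 22.7 in animal 3, 21.1 in animal 5 and 20.5 in animal 10. Contralateral Lgals3 in the same order was 22.1, 32.2, 14.3, 35.9, 41.8, 17.3, 21.9, 18.7, 9.46 and 9.01. No value lay between 22.7 and 174 ipsilaterally. Ipsilateral Cd68 in the same order of animals was 218, 225, 301, 206, 112, 224, 86.9, 16.2, 21.1 and 23.4 scaled counts.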
